A study of Mus musculus with 6 samples.

How the data were processed

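Pancreatic islets of 12-week-old mice were profiled by bulk RNA-seq in 6 libraries. Per the labels' protocols, pancreata were digested with collagenase, islets were purified on a density gradient and picked by hand, and total RNA was made into Illumina TruSeq cDNA libraries that were sequenced on a HiSeq2000 as single-end reads of 100 bp. Islets hold beta cells and other endocrine cells, and hand-picked islets can carry acinar, duct, endothelial, stromal, nerve and immune cells, so a change in a transcript can lie in its level per cell or in the share of cells.

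The authors deposited whole-number counts per gene for each library and a table of their own comparison. Per the submitters' processing notes, bcl2fastq 1.8.4, TopHat2 2.1.0, Cufflinks 2.0.2 and DESeq (with no version) were used with the mouse genome build mm9, and the role and order of each tool are not stated there. The read counter, the annotation and the use of strand are not given in the sources used here, so overlapping genes, antisense genes and near copies such as Ins1 and Ins2 could not be told apart further than the counts allow. In the authors' deposited table the mean of the size-factor scaled counts per group, a ratio (fold change), its log2 value and p-values with adjusted p-values are given for 23284 genes. The mean counts of that table were equal to the deposited counts divided by size factors recomputed here, to within rounding. None of the files had a separate line for unassigned reads. Symbols starting with mt-, which mark mitochondrially encoded genes, took 0% of the counts in each of the 6 libraries, and such genes were not analysed here. Gene symbols are those of the files. Because the reference at hand was assembly GRCm38 and the files use mm9, no coordinates are given, and the RefSeq gene table of GRCm38.p6 was used only for the order of neighbouring genes.

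Libraries were grouped by the titles in the labels into knockout (replicates 4, 5 and 6) and control (replicates 7, 10 and 16). The groups share no replicate number, so no pairing was used. Controls carried no Cre, so an effect of Cre or of its transgene cannot be told apart from that of the Neurod1 deletion. Total counts ranged from 12206393 to 20412435 per library, and replicate libraries differed by far more than sampling noise (chi-square per degree of freedom from 16.9 to 44.2 over 6 pairs of replicates), so none was taken as a repeat of another. Pearson correlations of log2 CPM were 0.977 to 0.989 between libraries of 1 genotype and 0.935 to 0.961 between genotypes. The ribosomal RNA precursor Rn45s took 2.56%, 0.324% and 3.58% of the counts in knockout libraries 4, 5 and 6 and 0.396%, 1.69% and 0.637% in control libraries 7, 10 and 16.

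Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with default settings (minimum count 10, minimum total count 15), which left 14770 of 23284 genes. Libraries were scaled by TMM factors (0.988 to 1.021), dispersions were estimated with robust settings, and groups were compared by the quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of genes are from this model unless another tool is named. Standard errors of log2 fold changes were derived from the same fit. CPM values in the text are counts per 1e+06 counts, with library sizes scaled by the TMM factors unless stated otherwise. The biological coefficient of variation was 14.2%. In all, 5537 genes had an unadjusted p under 0.05.

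A total of 26 gene lists of islet cell types, pathways and responses were fixed before the data were examined, and 25 of them had more than 1 tested member. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over the lists, and again with an estimated correlation and with the rotation test fry. For each list, members past the genome-wide threshold and members past the threshold adjusted over the list alone were counted. Wnk3 and Sertm1 were not matched by symbol and 21 list members had too few counts to be tested. The lists share some genes, such as Sox9, Ldha, Pcsk1 and Nkx2-2. The genes named in the report followed a rule also fixed before the data were examined: Neurod1; the 12 genes with the largest change in each direction that passed the threshold, had at least 5 CPM on average in the higher group and had no overlap between groups; up to 4 members of each list with the smallest p past the threshold, or where none passed the 1 or 2 most abundant; and the hormone genes. Genes named beyond these, as further members of a list, were chosen after their values were seen. Some genes that the rule selects are not reported here.

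The tests were checked on simulated counts made from the means and library sizes of the 14770 genes, with 100 genes changed 1.5-fold and 100 changed 2-fold. For the comparison of knockout with control, edgeR recovered 36% of the 1.5-fold and 71% of the 2-fold changes, and 9.3% of its calls were false. DESeq2 recovered 46% and 75% with 22.9% false calls, and limma-voom 36% and 69% with 8% false calls. In the data 24.4% of the tested genes were called, a far larger share than was changed in the simulation. Adjusted p-values depend on that share, so these recovery and false-call percentages do not carry over to the data. A simulated raised list was called and 0 of the unchanged lists were called by camera with either correlation or by fry. The simulated counts carried no correlation between members of a list. In the data the estimated correlation ran from -0.078 for the immature beta cell markers to 0.717 for the acinar markers. The simulation therefore cannot show how often camera with a preset correlation calls unchanged lists whose members are correlated.

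Alternatives tried were size factors, upper-quartile factors or library size alone in place of TMM, no filter or a filter of 1 CPM in 3 libraries, library sizes without hormone and acinar genes, non-robust estimation, the mean level of the acinar markers as a covariate, each library left out in turn, DESeq2 1.42.0, limma-voom, and a test against a fold of 1.5 (glmTreat). The level of Rn45s and the mean level of the leukocyte markers as covariates were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.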

Results

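RNA-seq libraries of isolated pancreatic islets were compared between mice that lack Neurod1 in beta cells and control mice, all 12 weeks old. Neurod1 is a basic helix-loop-helix transcription factor of endocrine cells and neurons. In the knockout group both Neurod1 alleles carried loxP sites and a Cre recombinase driven by the rat insulin promoter (Rip-Cre) was present. The control group carried the floxed alleles without Cre. Each group had 3 libraries, numbered 4, 5 and 6 in the knockout and 7, 10 and 16 in the control. Total counts per library were 16473159, 15063943 and 12206393 in the knockout (mean 14.58 ± 2.17 in units of 1e+06 counts, SD, n = 3) and 19608819, 20412435 and 14424767 in the control (mean 18.15 ± 3.25 in units of 1e+06 counts, SD, n = 3). Between 17564 and 18103 genes had at least 1 count in a library. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these samples. Xist was at 1415 counts per 1e+06 counts (CPM, here without the TMM factors) or more in each of the 6 libraries. None of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had more than 4 counts in any library.

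Neurod1 itself was lower in every knockout library than in every control library. It had 463, 444 and 389 counts in knockout libraries 4, 5 and 6, and 3839, 3614 and 2049 counts in control libraries 7, 10 and 16. This was 29.8 ± 1.41 CPM in the knockout and 172 ± 29.2 CPM in the control (SD, n = 3 each). The log2 fold change was -2.53 (SE 0.13), a 5.78-fold fall, with an adjusted p of 1.74e-05 by edgeR's quasi-likelihood test. Counts per gene do not show which part of the transcript was deleted.

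The comparison asked which islet transcripts differ when beta cells lack Neurod1. The largest rises were in Aldh1a3, a retinaldehyde dehydrogenase used as a marker of dedifferentiated beta cells (3.33 ± 1.07 CPM in control, 476 ± 239 CPM in knockout, SD, n = 3 each), and in Lrrc55, an auxiliary potassium channel subunit (2.27 ± 1.32 and 240 ± 22 CPM). Their log2 fold changes were 7.18 (SE 0.56, adjusted p = 0.00131) and 6.78 (SE 0.33, adjusted p = 1.08e-04). Further rises were in Adamts16 (5.90), the lipase gene Lipc (5.78), Moxd1 (5.54), the potassium channel Kcnk9 (5.40), the chloride channel Cftr (5.26), the glutamate decarboxylase Gad2 (4.78), the apelin receptor Aplnr (4.49), the potassium channel Kcnj13 (4.38) and the opioid peptide precursor Pdyn (4.32). Moxd1 missed the threshold with limma-voom (5.52, adjusted p = 0.0607). The largest falls were in Msln, which encodes mesothelin (31.0 ± 4.13 CPM in control, 0.619 ± 0.164 CPM in knockout, log2 fold change -5.63, SE 0.20, adjusted p = 3.04e-06), and in Kcnf1, a potassium channel subunit (-4.59, SE 0.27). Further falls were in the proton pump gene Atp4a (-3.91), Mlph, which links granules to myosin (-3.86), Gm4791 (-3.69), Cyp4f39 (-3.66), the insulin gene Ins1 (-3.50), Olfm4 (-3.45), the cation channel Trpc4 (-3.38), the nucleotide receptor P2ry6 (-3.32), T2 (-3.01) and the galanin receptor Galr1 (-2.91). For each of these genes all 3 knockout libraries lay beyond all 3 control libraries, which was part of the rule that chose them. Among the 14770 genes tested, 1736 were higher and 1864 lower in the knockout at an adjusted p under 0.05 (24.4% of those tested). At least a 2-fold difference was found for 365 of the higher and 485 of the lower genes, and at least a 4-fold difference for 102 and 73. In a principal component analysis the first component held 57.8% of the variance and parted the genotypes. Acinar marker genes took 4.01 ± 2.14% of the counts in control and 1.14 ± 0.55% in knockout libraries (SD, n = 3 each). With the acinar marker level as a covariate, 795 genes were higher and 665 lower, and 1250 of the 3600 genes were called again. Without control library 10, 1153 genes were higher and 1225 lower.

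**Figure D1:**
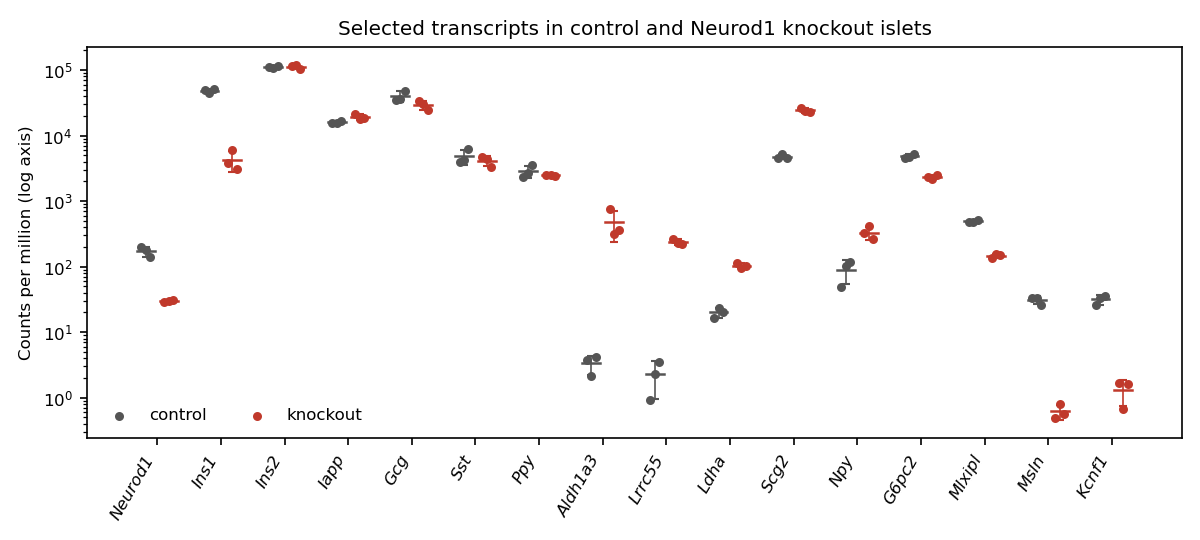
CPM (log axis) of 16 transcripts in control (grey) and Neurod1 knockout (red) islets. Points are libraries, 3 per group, horizontal bars are means and error bars are SDs. Neurod1 lay at 172 CPM in control and 29.8 CPM in knockout, and Ins1 at 48668 and 4307 CPM, while the Ins2 points of the groups overlap.

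Ins1 had 48668 ± 3300 CPM in control and 4307 ± 1529 CPM in knockout islets (SD, n = 3 each), an 11.3-fold fall (log2 fold change -3.50, SE 0.25, adjusted p = 1.27e-04). Ins2 had 111010 ± 5361 and 113090 ± 7417 CPM, a log2 difference of 0.03 (SE 0.10, adjusted p = 0.873). Ins1 and Ins2 are near copies, and how reads that match both were counted is not given in the sources used here, so both values carry that uncertainty. Iapp, the islet amyloid peptide that is secreted with insulin, differed by 0.28 (SE 0.10, adjusted p = 0.0797). Gcg, the glucagon gene, differed by -0.45 (SE 0.16, adjusted p = 0.0663), Sst by -0.21 (adjusted p = 0.498) and Ppy by -0.20 (adjusted p = 0.346), none of which passed the test. DESeq2 called Iapp (0.29, adjusted p = 0.00192) and Gcg (-0.44, adjusted p = 0.00927), and edgeR with upper-quartile factors called Gcg (-0.49, adjusted p = 0.0484).

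Genes of beta cell identity and maturity moved both ways. Of 23 members 8 rose, 7 fell and 8 did not pass. Adjusted over the list alone, 9 rose and 7 fell. Pcsk1, a proinsulin convertase, rose from 453 ± 32.5 to 1165 ± 110 CPM (SD, n = 3 each, log2 fold change 1.36, SE 0.10), and Ero1lb, an oxidase of disulfide formation in the endoplasmic reticulum, rose 2.93-fold (1.55, SE 0.14). The other rises were in Glp1r (1.10), the prolactin receptor Prlr (0.98), Pdx1 (0.93), Sytl4 (0.67), Nkx6-1 (0.47) and the glucose transporter Slc2a2 (0.35). G6pc2, a glucose-6-phosphatase subunit of beta cells, fell from 4806 ± 383 to 2344 ± 182 CPM (-1.04, SE 0.10). Besides Ins1, the channel Trpm5 (-1.35), Nkx2-2 (-0.80), Adcyap1r1 (-0.62), Rfx6 (-0.55) and the zinc transporter Slc30a8 (-0.53) also fell. Mafa (0.27) and Ucn3 (0.13) did not pass. Without control library 10 or 16, 5 members rose, and with the acinar marker level as a covariate 6 rose and 2 fell. The list as a whole did not pass camera (adjusted p = 0.848), and its median was 0.13 while its mean was -0.059. Camera tests for a shift in 1 direction, so it does not speak to members that move both ways. The mixed form of fry, which allows both directions, gave an adjusted p of 1.24e-05 for this list. That form called 21 of the 25 lists tested.

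Genes of the secretory granule and of exocytosis also split. Of 18 granule and prohormone processing genes, 7 rose, 6 fell and 5 did not pass, with the same counts adjusted over the list alone. Scg2, a granin, rose 5.07-fold, from 4769 ± 384 to 24181 ± 1989 CPM (SD, n = 3 each, log2 fold change 2.34, SE 0.11, adjusted p = 9.36e-06), and the amidating enzyme Pam rose by 0.80 (SE 0.08). Pcsk1n, an inhibitor of the convertase Pcsk1, fell by 1.2 (SE 0.13). Of 22 genes of stimulus-secretion coupling and exocytosis, 4 rose, 7 fell and 11 did not pass, and 5 rose and 8 fell adjusted over the list alone. The syntaxin gene Stx1a fell from 20.6 ± 0.854 to 11.3 ± 0.555 CPM (-0.87, SE 0.10), while the SNARE gene Snap25 rose from 186 ± 11.5 to 387 ± 17.9 CPM (1.05, SE 0.08) and Cask rose by 0.92 (SE 0.09). The channel subunits Abcc8 (0.08) and Kcnj11 (0.07), which form the ATP-sensitive potassium channel, did not pass. Without knockout library 4, 4 exocytosis genes fell. The acinar marker level as a covariate left 5 granule genes higher and 3 lower, and 2 exocytosis genes higher and 3 lower. Neither list passed camera (adjusted p = 0.433 and 0.848).

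Of 23 islet transcription factors 3 rose, 6 fell and 14 did not pass, and 4 rose and 7 fell adjusted over the list alone. Mlxipl, the carbohydrate response factor ChREBP, fell 3.36-fold, from 493 ± 21.3 to 147 ± 10.9 CPM (SD, n = 3 each, log2 fold change -1.75, SE 0.08, adjusted p = 9.36e-06). Nkx2-2 (-0.80, SE 0.14), Rfx6 (-0.55, SE 0.09) and Foxa2 (-0.35, SE 0.08) fell as well. Foxa2 missed the threshold without control library 7 (-0.31, adjusted p = 0.0521). The number of factors that rose was 1 without knockout library 5 or 6 and 0 without control library 10 or 16, and 1 factor fell with the acinar marker level as a covariate. The list did not pass camera (adjusted p = 0.180).

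Of 11 immature or dedifferentiated beta cell markers 2 rose (Aldh1a3 and Npy), 2 fell (Sox9 and Fev) and 7 did not pass, and 2 rose and 3 fell adjusted over the list alone. Npy, a neuropeptide of fetal beta cells, rose 3.69-fold, from 89.8 ± 35.8 to 331 ± 75.8 CPM (SD, n = 3 each, log2 fold change 1.89, SE 0.38). Sox9, a progenitor and duct factor, was at -1.16 (SE 0.29) and Fev at -0.58 (SE 0.16). Npy missed the threshold without knockout library 4, knockout library 5 or control library 10 (adjusted p from 0.07 to 0.072), Sox9 without control library 7 or 10 (0.0557 and 0.0782), and Fev without any 1 library except control library 10 (0.0616 to 0.107). Among 20 genes that adult beta cells normally repress, 4 rose, 2 fell and 14 did not pass, and 4 rose and 3 fell adjusted over the list alone. The lactate dehydrogenase gene Ldha rose 5.21-fold, from 20 ± 3.34 to 104 ± 9.05 CPM (2.38, SE 0.13, adjusted p = 2.04e-05). Igfbp4 (0.84, SE 0.14) and C1qbp (0.43, SE 0.09) also rose, and Cxcl12 (-0.70, SE 0.10) and Yap1 (-0.45) fell. The lactate transporter Slc16a1 (-0.07) and the hexokinase Hk1 (0.13) did not pass. The number of repressed genes that fell was 1 without knockout library 5 or 6 or control library 10 or 16. Once the acinar marker level was a covariate, 1 immature marker rose and 0 fell, and 1 repressed gene rose and 2 fell. Neither list passed camera (adjusted p = 0.335 for the immature and 0.822 for the repressed genes).

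Markers of the other endocrine cells had few calls. Of 12 alpha cell markers Irx1 (-0.48, SE 0.14) passed, of 7 delta cell markers Rbp4 (0.48, SE 0.12) and Hhex (-0.33, SE 0.10) passed, and of 4 markers of PP and epsilon cells Tmem100 (-1.26, SE 0.34) passed. Adjusted over the list alone, 0 alpha markers, 1 higher and 2 lower delta markers and 1 lower PP or epsilon marker passed. Each of these 4 genes missed the threshold without at least 4 of the 6 single libraries (highest adjusted p = 0.142 for Irx1, 0.0774 for Rbp4, 0.123 for Hhex and 0.0886 for Tmem100). With all libraries and no covariate the lists did not pass camera (adjusted p = 0.126, 0.335 and 0.186). The alpha cell list passed without control library 10 (median -0.33, adjusted p = 0.0490), and the PP and epsilon cell list passed with the acinar marker level as a covariate (median -0.85, adjusted p = 0.0262).

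Markers of cells outside the endocrine islet were lower for 3 cell types. Endothelial markers fell together: of 15 members 11 fell, 4 did not pass and 0 rose, and 13 fell adjusted over the list alone. Their median log2 fold change was -0.51. The endothelial receptors Tie1 (46.7 ± 1.96 to 28.5 ± 2.77 CPM, SD, n = 3 each, -0.71, SE 0.09), Robo4 (-0.67, SE 0.09) and Flt1 (-0.56, SE 0.08) and the adhesion gene Esam (-0.76, SE 0.10) were examples. Camera gave an adjusted p of 8.29e-06, and the adjusted p was 0.528 with an estimated correlation. The number that fell was 7 with the acinar marker level as a covariate, where the median was -0.62 and the list passed camera (adjusted p = 2.25e-05). Acinar markers had a median of -1.86 with large spread between libraries. Of 31 members 2 fell, the acinar factors Ptf1a (1.69 ± 0.546 to 0.229 ± 0.151 CPM, -2.86, SE 0.51) and Rbpjl (-1.80, SE 0.51), 29 did not pass, and 1 fell adjusted over the list alone. This count depended on the estimation, since DESeq2 called 25 members lower and 1 higher and edgeR without robust estimation called 23 lower. Acinar genes took 5.67%, 4.77% and 1.6% of the counts in control libraries 7, 10 and 16, and 0.55%, 1.66% and 1.21% in knockout libraries 4, 5 and 6. Without control library 16, 21 acinar markers fell, and without knockout library 4, 6 or control library 7 or 10, 1 fell. Rbpjl missed the threshold without knockout library 4 or 6 or control library 7 or 10 (adjusted p from 0.0551 to 0.135). Trypsin and amylase genes of this list belong to families of near copies and are uncertain one by one. For the acinar list camera gave an adjusted p of 1.25e-05, and the adjusted p was 0.660 with an estimated correlation.

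Of 16 stellate cell and fibroblast markers 4 fell and 12 did not pass, and 6 fell adjusted over the list alone (median -0.55). They were Thy1 (-0.62, SE 0.15), Sparc (-0.43, SE 0.12) and the collagen genes Col3a1 (-0.56, SE 0.16) and Col1a1 (-0.80, SE 0.22). The adjusted p by camera was 0.00675, and the adjusted p was 0.615 with an estimated correlation. The count of 4 became 0 without knockout library 6 or control library 10, 1 without control library 16, 7 without control library 7 and 2 with the acinar marker level as a covariate, where the median was -0.79 and the list passed camera (adjusted p = 6.86e-04). Thy1 missed the threshold without knockout library 6 or control library 10 (highest adjusted p = 0.0625), and Sparc, Col3a1 and Col1a1 each missed it without 4 single libraries (highest adjusted p = 0.0891, 0.107 and 0.142).

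Of 14 duct markers 3 rose, 4 fell and 7 did not pass, and 5 rose and 5 fell adjusted over the list alone. Cftr rose 38.3-fold (1.52 ± 0.158 to 58.2 ± 20.2 CPM, SD, n = 3 each, log2 fold change 5.26, SE 0.36) and the bicarbonate transporter Slc4a4 rose by 0.83 (SE 0.15), while the mucin Muc1 (-1.44, SE 0.16) and Tspan8 (-0.55, SE 0.09) fell. Without knockout library 4, 5 duct markers rose, and without control library 10 or with the acinar marker level as a covariate, 2 fell. Of 12 Schwann cell and neuron markers 2 rose, 3 fell and 7 did not pass, with the same counts adjusted over the list alone. Th, the rate-limiting enzyme of catecholamine synthesis, fell 4.75-fold (37.0 ± 8.62 to 7.85 ± 1.18 CPM, -2.25, SE 0.19), and the intermediate filament gene Prph fell by 1.30 (SE 0.22). The nerve growth factor receptor Ngfr rose by 2.60 (SE 0.44). Ngfr missed the threshold without control library 7 or 10 (adjusted p = 0.0516 and 0.0633). The number of Schwann cell and neuron markers that rose was 0 without control library 10 and 1 without knockout library 4 or 5 or control library 7 or 16, and with the acinar marker level as a covariate 0 rose and 1 fell. The Schwann cell and neuron list passed camera without knockout library 5 (median -0.66, adjusted p = 0.0420). Of 20 leukocyte markers Cd14 fell (-0.89, SE 0.24), 19 did not pass and 0 passed adjusted over the list alone. Cd14 missed the threshold without knockout library 5 or 6 or control library 10 or 16 (highest adjusted p = 0.0942), while 3 leukocyte markers were lower without knockout library 4 and 2 with the acinar marker level as a covariate. The mean log2 level of the leukocyte markers was 4.15, 3.23 and 4.27 in knockout libraries 4, 5 and 6 and 3.71, 4.10 and 3.06 in control libraries 7, 10 and 16. With all libraries these 3 lists did not pass camera (adjusted p = 0.848, 0.186 and 0.953). Of the adipocyte markers 1 was tested, Fabp4 (-0.55, SE 0.38, adjusted p = 0.348), so that list had no test.

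**Figure D2:**
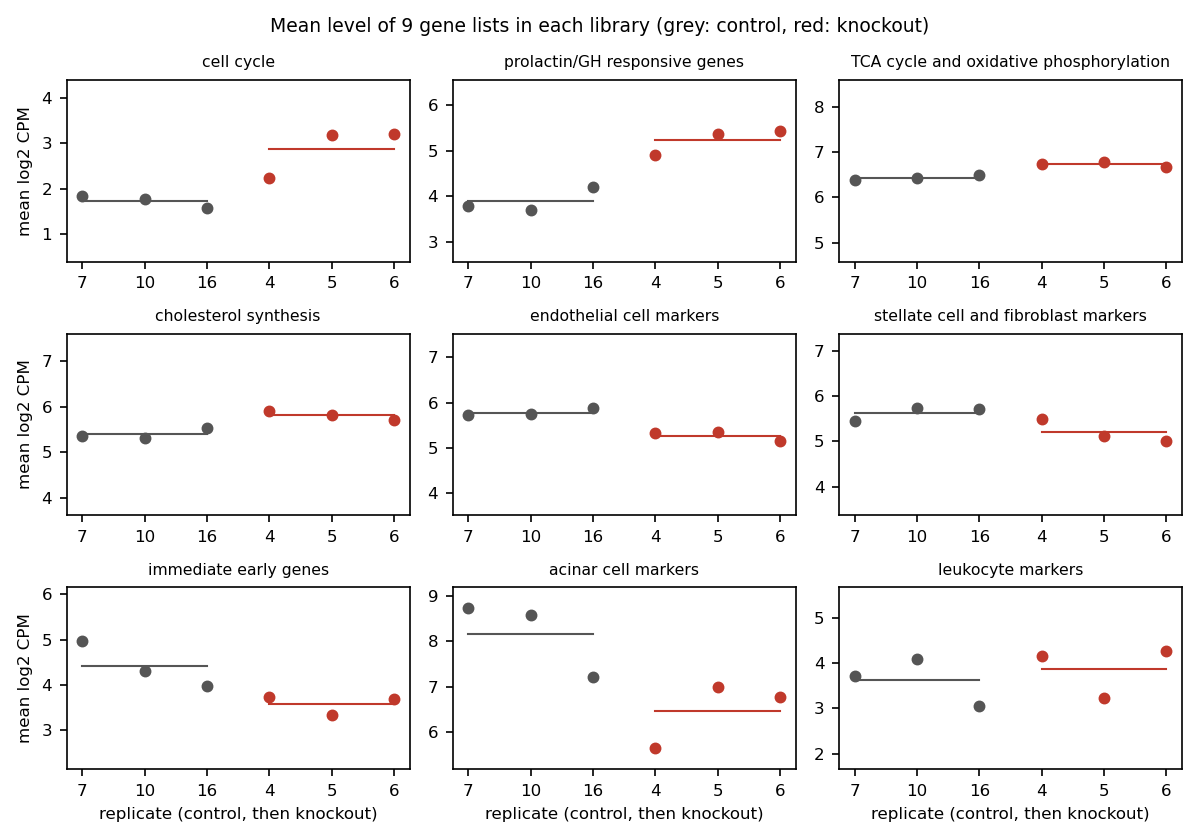
Mean log2 CPM of the members of 9 gene lists in each library (grey for control replicates 7, 10 and 16, red for knockout replicates 4, 5 and 6), with horizontal lines at the group means. Each panel spans 4 log2 units around its own middle. The cell cycle list lay at 2.23, 3.18 and 3.21 in the knockout libraries and at 1.83, 1.77 and 1.57 in the control libraries.

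Cell cycle genes were higher in knockout islets. Of 25 members 18 rose, 7 did not pass and 0 fell, and 24 rose adjusted over the list alone. All 25 log2 fold changes were above 0 and the median was 1.19. Cenpf, a kinetochore protein, rose 4.55-fold (2.53 ± 0.349 to 11.6 ± 5.50 CPM, SD, n = 3 each, log2 fold change 2.18, SE 0.37), the cyclin Ccnb1 rose 4.78-fold (2.26, SE 0.43), the mitotic kinesin Kif11 by 1.68 (SE 0.36) and the replication helicase subunit Mcm5 by 1.19 (SE 0.25). Levels were low in both groups, and Ki67, encoded by Mki67 (1.95), did not pass. Camera gave an adjusted p of 6.09e-08, and the adjusted p was 0.538 with an estimated correlation. The number of members that rose was 8 without knockout library 5 or 6, 10 without control library 7, 9 without control library 10 and 7 without control library 16, and limma-voom called 11. With the acinar marker level as a covariate 18 rose and the median was 2.0. Kif11 missed the threshold without control library 10 (1.63, adjusted p = 0.0501).

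Genes that respond to prolactin and growth hormone in islets were higher as well. Of 12 members 6 rose, 6 did not pass and 0 fell, with the same counts adjusted over the list alone, and the median was 0.57. Matn2, a matrix protein, rose 16.1-fold (67.5 ± 27.6 to 1081 ± 210 CPM, SD, n = 3 each, log2 fold change 4, SE 0.35). The tight junction gene Cldn8 rose 15.2-fold (3.93, SE 0.34), Tph2, a tryptophan hydroxylase of serotonin synthesis, rose 12.1-fold (3.59, SE 0.57), and Ehhadh rose by 0.54 (SE 0.10). The feedback inhibitors Cish (0.28), Socs2 (0.15) and Socs3 (-0.28) did not pass. The adjusted p by camera was 0.001, and the adjusted p was 0.528 with an estimated correlation. The median was 0.87 without control library 10, and with the acinar marker level as a covariate 3 members rose, the median was 0.80 and the list passed camera (adjusted p = 0.00933).

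Of 26 genes of the TCA cycle and oxidative phosphorylation 15 rose, 11 did not pass and 0 fell, with the same counts adjusted over the list alone (median 0.25). Fh1, which encodes fumarase, rose 2.75-fold (61.1 ± 3.77 to 168 ± 28.1 CPM, SD, n = 3 each, log2 fold change 1.46, SE 0.12), Cox5a rose by 0.69 (SE 0.09), Pcx, which encodes pyruvate carboxylase, by 0.60 (SE 0.10) and Ndufa4 by 0.55 (SE 0.06). Camera gave an adjusted p of 8.29e-06, and the adjusted p was 0.528 with an estimated correlation. The number that rose was 9 without knockout library 5, 8 without control library 10 and 3 with the acinar marker level as a covariate, where the median was 0.22 and the list passed camera (adjusted p = 0.00404). Of 13 cholesterol synthesis genes 10 rose, 3 did not pass and 0 fell, and 11 rose and 1 fell adjusted over the list alone (median 0.46). Insig1 (70.6 ± 11.8 to 130 ± 18.1 CPM, 0.89, SE 0.14), Sqle (0.57, SE 0.07), Lss (0.46, SE 0.09) and the regulator Srebf2 (0.35, SE 0.06) were among them. The adjusted p by camera was 1.14e-04, and the adjusted p was 0.528 with an estimated correlation. The number that rose was 6 without control library 7, 5 without control library 10 and 2 with the acinar marker level as a covariate, where the median was 0.32 and the list passed camera (adjusted p = 0.0262). Hmgcs1 of the cholesterol list and Eno1 of the glycolysis list were listed at 0 or 1 count in every library and were not tested.

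Of 17 glycolysis genes 2 rose, 3 fell and 12 did not pass, with the same counts adjusted over the list alone. Ldha (2.38) and Pgk1 (0.57, SE 0.10) rose, and Eno2 (-0.72, SE 0.08), Gpi1 (-0.19, SE 0.06) and Pfkl (-0.22) fell. Gpi1 missed the threshold without any 1 of the 6 libraries (adjusted p from 0.0612 to 0.162). The number of glycolysis genes that fell was 2 without control library 7, 1 without any other single library, and 1 with DESeq2, with size factors or library size alone in place of TMM, with library sizes without hormone and acinar genes or with no filter, and with the acinar marker level as a covariate 1 rose and 1 fell. Of 14 hypoxia response genes 2 fell and 12 did not pass, with the same counts adjusted over the list alone. Ndrg1 fell 2.58-fold (197 ± 16.4 to 76.4 ± 3.03 CPM, SD, n = 3 each, log2 fold change -1.37, SE 0.08, adjusted p = 2.15e-05) and Ankrd37 fell by 0.69 (SE 0.18). Ankrd37 missed the threshold without knockout library 4 or 6 or control library 10 or 16 (highest adjusted p = 0.0812). The hypoxia list passed camera without knockout library 4 (median -0.30, adjusted p = 0.0417) and with the acinar marker level as a covariate (median -0.40, adjusted p = 0.0262). Of 15 oxidative stress response genes 4 rose, 1 fell and 10 did not pass, and 5 rose and 1 fell adjusted over the list alone. Txnip, a thioredoxin inhibitor induced by glucose, rose by 1.53 (SE 0.29), Gpx1 by 0.70 (SE 0.12) and Prdx1 by 0.42 (SE 0.07), while the heme oxygenase Hmox1 fell by 1.44 (SE 0.23). Without control library 7 or 10, 2 oxidative stress genes rose, and with the acinar marker level as a covariate 0 rose and 0 fell. Txnip missed the threshold without control library 7 or 10 (adjusted p = 0.0531 and 0.0551). With all libraries and no covariate these 3 lists did not pass camera (adjusted p = 0.934, 0.154 and 0.180).

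Of 23 genes of the unfolded protein response 11 rose, 5 fell and 7 did not pass, with the same counts adjusted over the list alone. Chaperones and degradation factors of the endoplasmic reticulum were among those that rose, with Calr at 1007 ± 43.8 CPM in control and 1573 ± 119 CPM in knockout (SD, n = 3 each, log2 fold change 0.64, SE 0.09), Edem1 at 0.78 (SE 0.10) and Hspa5 at 0.61. Asparagine synthetase, encoded by Asns (-1.01, SE 0.14), the pseudokinase Trib3 (-2, SE 0.31), Chac1 (-2.27) and the transcription factor Atf4 (-0.36) fell. With the acinar marker level as a covariate 1 member rose and 0 fell, and the median went from 0.37 to 0.18. The list did not pass camera (adjusted p = 0.154). Of 14 immediate early genes 4 fell, 10 did not pass and 0 rose, with the same counts adjusted over the list alone (median -0.84). The phosphatase Dusp1 fell from 53.0 ± 5.12 to 24.7 ± 4.53 CPM (-1.10, SE 0.13), Zfp36 fell by 0.72 (SE 0.10), Ier2 by 0.91 (SE 0.19) and Egr1 by 1.26 (SE 0.33). Egr1 missed the threshold without knockout library 4, 5 or 6 or control library 10 (adjusted p from 0.0940 to 0.149). Camera gave an adjusted p of 0.00462, and the adjusted p was 0.538 with an estimated correlation. The median was -0.53 without control library 7, and with the acinar marker level as a covariate it was -0.41 with 1 member lower (adjusted p = 0.198). Of 14 interferon response and MHC class I genes 0 passed at the adjusted threshold with edgeR, genome-wide or adjusted over the list alone, and H2-D1 (0.02) and H2-K1 (0.27) were its most abundant members. H2-K1 passed without knockout library 5 (0.37, adjusted p = 0.0377), and 2 members other than H2-K1 were higher without control library 10. That list did not pass camera (adjusted p = 0.926).

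**Figure D3:**
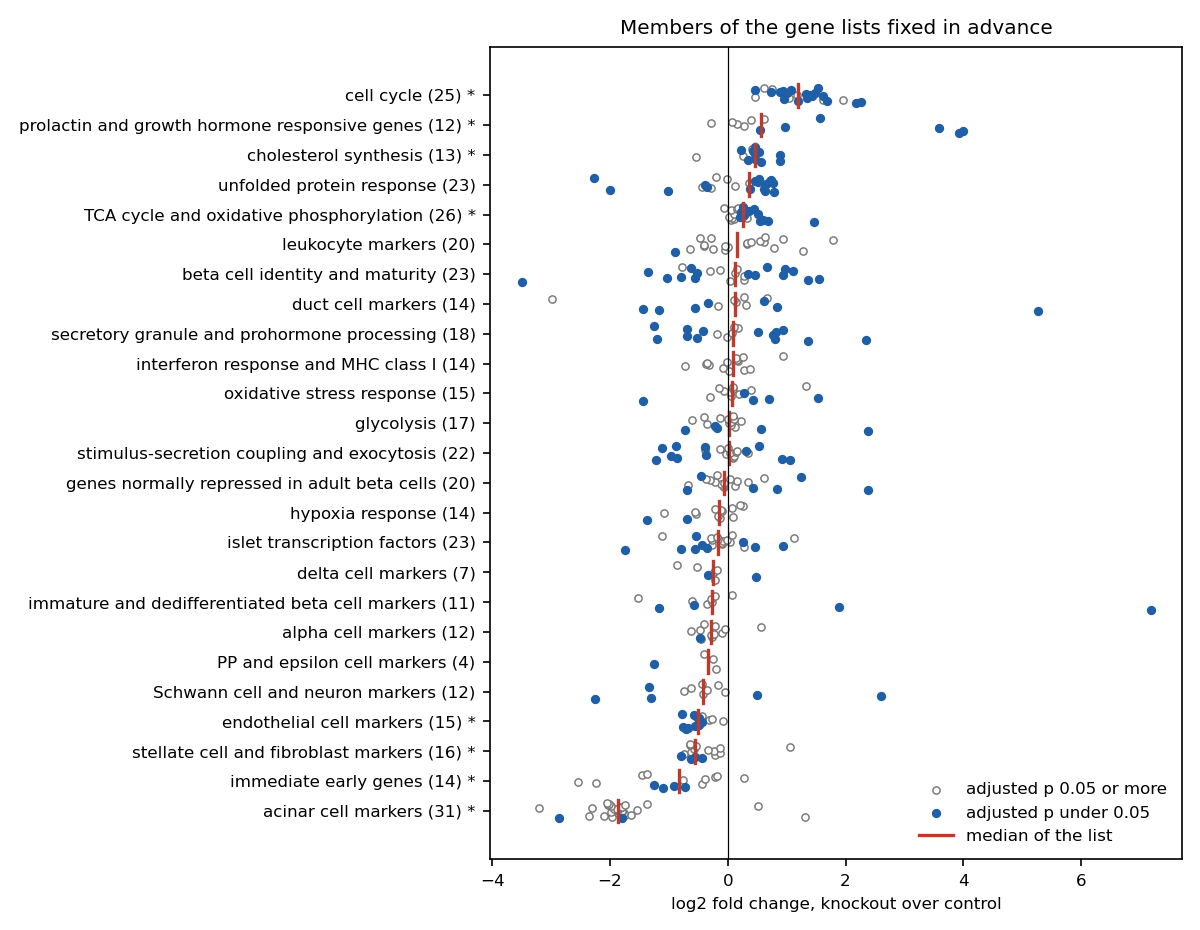
Log2 fold changes (knockout over control) of the tested members of 25 gene lists, with the number tested in brackets. Filled points passed an adjusted p of 0.05 in edgeR, open points did not, red bars are list medians and an asterisk marks the 8 lists that passed camera with a preset correlation. Medians of these 8 lists ran from -1.86 for acinar markers to 1.19 for cell cycle genes.

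Of the 25 lists tested, 8 passed camera with a preset correlation, 4 higher and 4 lower. With an estimated correlation 0 of the 25 passed (smallest adjusted p = 0.53). The rotation test fry called 8 lists, of which 5 were among those called by camera, and the acinar, stellate and cell cycle lists were not (adjusted p = 0.111, 0.0914 and 0.0566). The other 3 lists that fry called were the alpha cell and hypoxia lists, both lower (adjusted p = 0.0373 and 0.0225), and the oxidative stress list, higher (adjusted p = 0.0333). Of the 101 named genes past the threshold, 80 passed without any 1 library and 62 passed with the acinar marker level as a covariate. Those that did not pass with that covariate included T2, Igfbp4, C1qbp, Sox9, Npy, Fev, Rfx6, Nkx2-2, Foxa2, Irx1, Rbp4, Hhex, Tmem100, Ptf1a, Rbpjl, Thy1, Sparc, Col3a1, Col1a1, Prph, Ngfr, Calr, Asns, Trib3, Pgk1, Gpi1, Pcx, Ankrd37, Hmox1, Prdx1, Gpx1, Txnip, Srebf2, Lss, Zfp36, Ier2, Egr1 and Tph2. The adjusted p of the 39 genes lost under it ran from 0.0505 to 0.568. Of these, 14 had a log2 fold change at least as large with the covariate and 25 a smaller one, a median of 90.8% of the log2 fold change was kept, and the median SE was 0.14 without and 0.24 with the covariate. The log2 fold change of Tph2 was 3.59 (SE 0.57) without and 3.5 (SE 0.97) with it, and that of Egr1 was -1.26 (SE 0.33) and -0.48 (SE 0.46).

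The authors' deposited table of the same comparison called 2498 genes at an adjusted p under 0.05, of which 1295 were higher and 1203 lower in the knockout. In the authors' deposited table Neurod1 had a log2 fold change of -2.51, Ins1 of -3.48 and Lrrc55 of 6.74. Of the 3600 genes called here, 2450 were also called in the authors' deposited table (68.1%, 95% exact binomial interval 66.5 to 69.6%), each in the same direction. That interval treats genes as independent, which they are not. Of its calls among the genes tested here, 98.6% were called here as well. Log2 fold changes of the 14768 genes with a finite value in both had a Spearman rho of 0.9998 across genes, which are not independent replicates and come from the same 6 libraries.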

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

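Outliers were not tested within the groups of 3 libraries, and the series has 1 comparison, so no result was singled out by a fixed rule. The 3 patterns weighed here are differences that stood out in the report. Tests on both insulin genes, the other beta cell genes, Cish, Socs2 and Socs3, and single knockout libraries were chosen after the results were seen.

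Ins1 fell by 3.5 on the log2 scale while Ins2 did not pass the test. If reads of Ins1 had only been counted for its near copy, Ins2 would have gained at least 0.5 of the loss of Ins1, which dropped by 44361 CPM. The Ins2 difference, knockout minus control, was 2084 CPM (SE 5284), below 22181 CPM by more than 2 SE, which argues against misplaced reads as the whole cause. A lower share of beta cells in the knockout islets would have lowered the other beta cell genes alike, but the other 22 members of that list had a median log2 fold change of 0.14 (SD 0.80). An Ins1-specific dependence on Neurod1 is therefore a hypothesis, and an effect of the insulin-promoter Cre transgene on Ins1 could not be tested without Cre-positive controls.

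Of 12 genes that respond to prolactin and growth hormone 6 rose, among them Matn2, Cldn8 and Tph2, with a list median of 0.57. Some insulin-promoter Cre transgenes carry a growth hormone gene that may act on islets, and the labels do not say which line was used. The mean level of the feedback genes Cish, Socs2 and Socs3 differed by 0.13 (SE 0.46), but the largest difference between a knockout and a control library was 1.34, so a 2-fold rise was not excluded and the transgene cannot be told apart from the Neurod1 deletion, since every knockout library carries both. Tph1, left out of the test for low counts, had 9, 43 and 11 counts in knockout libraries 4, 5 and 6 and 0, 1 and 3 in control libraries 7, 10 and 16. Fgf21, the other member left out for low counts, went the other way. It had 4, 1 and 1 counts in the same knockout libraries and 6, 18 and 6 in the same control libraries.

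Of 25 cell cycle genes 18 rose and all 25 had a positive log2 fold change, with a median of 1.19. Dividing leukocytes were 1 candidate source, since leukocyte markers varied between libraries. With their level as a covariate the cell cycle median was 1.15, with 16 members called and an adjusted p of 1.2e-07 by camera with a preset correlation. Without the covariate the camera adjusted p was 0.538 with an estimated correlation. The leukocyte level itself differed by 0.26 between genotypes (SE 0.45), and the covariate moved the log2 fold changes of all genes by a median of 0.026. It could thus hardly lower the cell cycle median, and it does not measure how many leukocytes divide. The test therefore cannot decide whether dividing leukocytes were the source. Leaving out 1 knockout library gave medians of 1.5 without library 4, 1.11 without library 5 and 1 without library 6. The rise thus did not rest on 1 library, but it was larger in knockout libraries 5 and 6 than in 4. Mean log2 levels of the list were 3.18, 3.21 and 2.23 in these, and 1.83, 1.77 and 1.57 in control libraries 7, 10 and 16. Without knockout library 5 or 6, 8 members were called. Which islet cells carry these transcripts stays open, because the libraries are of whole islets, and a biological change in proliferation remains a hypothesis.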

How the results depend on the processing

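Apart from the settings named next, 1570 to 2062 genes were higher and 1634 to 2095 lower in the knockout. With the acinar marker level as a covariate 795 were higher and 665 lower. That level itself differs between the genotypes. For the 39 named genes lost under it the median SE went from 0.14 to 0.24, and a median of 90.8% of the log2 fold change was kept. Against a fold of 1.5 (glmTreat), a stricter question by construction, 256 were higher and 261 lower. Leaving out 1 library gave 1153 to 1590 higher and 1225 to 1433 lower genes, the lowest of both without control library 10, with fewer samples in each fit. No gene called by both the original and an alternative fit changed sign. With Rn45s as a covariate, added after seeing the data, 3061 of the 3600 genes were called again, and with the leukocyte level, also added, 3221. Under other scalings the median of all genes lay within 0.038 of 0 and the share of higher genes among calls was between 42.8 and 55.2%. Neurod1 ranged from -2.66 to -2.16. With an estimated correlation 0 lists passed, and fry lost 3 of the lists called by camera and called 3 others. The acinar list had a median of 0.18 with its own level as covariate, which follows from the construction. Of 1962 values of named genes under alternatives, 1801 kept direction and side of the threshold, 147 missed the threshold, 4 newly passed it and 10 changed sign, of which 0 passed in either fit. These were Ins2 (-0.04 with the acinar covariate, -0.02 to 0.09 over the fits without 1 library), Sst (-0.33 to 0.02 over those fits) and H2-D1 (-0.01 with upper-quartile factors, -0.11 with Rn45s, -0.08 with the leukocyte level, -0.07 to 0.15 without 1 library). Of 400 list medians with camera under 16 other fits, 377 kept sign and side of the threshold, 1 missed the threshold, 5 newly passed it and 17 changed sign, of which 1, the acinar list, had passed. The other sign changes were in the exocytosis (-0.01) and glycolysis (-0.01) lists with upper-quartile factors, the transcription factor (0.03), duct (-0.01) and glycolysis (-0.04) lists with the acinar covariate, the leukocyte (-0.12) and interferon (-0.16) lists with Rn45s, and the same lists (-0.02 and -0.09) with the leukocyte level. Without 1 library the medians of the beta cell (-0.02 to 0.15), repressed (-0.14 to 0.12), interferon (-0.21 to 0.26) and glycolysis (-0.02 to 0.05) lists lay on both sides of 0. The cause of these changes was not tested. With 3 libraries a group, small changes can go uncalled. The simulated recovery of 36% at 1.5-fold does not measure how many, because far fewer genes were changed there than were called in the data.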

Other observations

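The tests of the splits, of neighbouring genes and of the amino acid genes not yet looked at were set before their results were seen, and the genes named in the next 2 paragraphs were chosen after their values were seen.

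Gipr, the receptor of the incretin GIP, fell from 171 ± 12.0 to 48.9 ± 0.940 CPM (SD, n = 3 each, log2 fold change -1.81, SE 0.07, edgeR adjusted p = 6.88e-06), and Vipr1, a receptor of vasoactive intestinal peptide, fell from 182 ± 12.2 to 41.1 ± 6.63 CPM (-2.15, SE 0.12). Glp1r (1.10) and the glucagon receptor Gcgr (0.83, SE 0.07) rose. The cannabinoid receptor Cnr1 fell by 1.15 (SE 0.16) and the GABA receptor subunit Gabbr2 rose by 1.46 (SE 0.21). Of the glutamate decarboxylases that make GABA, Gad1 fell from 117 ± 26.8 to 30.1 ± 9.54 CPM (-1.96, SE 0.29) and Gad2 rose from 0.721 ± 0.429 to 19.2 ± 4.61 CPM (4.78, SE 0.36). Adh1, an alcohol dehydrogenase, fell from 204 ± 16.7 to 34.0 ± 9.54 CPM (-2.59, SE 0.21), and Cyp26a1, which breaks down retinoic acid, rose by 4.55 (SE 0.41).

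Genes of the amino acid response, which the transcription factor Atf4 induces when amino acids are short, were lower in knockout islets. Of 12 members seen first 10 fell (median -1.08), among them Mthfd2 (-1.47), Slc7a5 (-0.82), Vldlr (-1.59) and Aldh1l2 (-2.32). Slc7a11 (1.33, SE 0.55, edgeR adjusted p = 0.133) and Ddit3 (-0.29, SE 0.12, adjusted p = 0.122) did not pass. Because their values were already known, these 12 are no independent support. The hypothesis that the fall extends to the rest of the response was then tested on 26 members not looked at before. Of these 14 fell and 2 rose (Wars at 0.70 and Slc3a2 at 0.33), with a median of -0.58. The serine synthesis enzyme Phgdh (-1.43), the transporters Slc1a4 (-1.78) and Slc6a9 (-1.61), Gpt2 (-0.81) and the tRNA synthetase genes Aars (-0.59) and Mars (-0.58) were examples. Camera with a preset correlation gave p = 8.6e-06, and with an estimated correlation p = 0.15. Without 1 library the median ran from -0.64 to -0.45. With the acinar marker level as a covariate it was -0.42, with 2 members lower and 1 higher (camera with a preset correlation, p = 0.0045). The acinar level itself differs between the genotypes, so this fit cannot tell whether part of the fall goes with the acinar content of the libraries.

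The 6 libraries can be split into 3 and 3 in 10 ways, and 1 of the 10, the genotype, called 3600 genes with edgeR. The highest of the 9 other splits was 0 genes, with 159 to 577 genes at an unadjusted p under 0.05 and 0 to 28 genes by DESeq2. Each of these 9 splits has both genotypes on each side, so the genotype difference adds to the spread within its groups. Few calls there follow from that mixing, so they do not show how many genes would be called without a genotype effect. With 10 splits no share under 0.05 can be reached.

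A further hypothesis was that DNA of another strain next to the Cre transgene, or another single locus, changes a crowd of neighbouring genes. By the gene order of GRCm38.p6, 89.6% of the tested genes were placed. Among the placed genes, 155 passed with a log2 fold change of at least 2 in size. The most crowded window of 50 neighbouring genes held 5 of these 155 genes. They were Lypd6b, Lypd6, Acvr1c, Upp2 and Dapl1 on chromosome 2. Random draws reached 5 often (permutation p = 0.28 over 1000 draws). Because 5 is also what 95% of draws stay within, a locus with fewer than 6 such genes would go unseen, so the test decides little and the threshold set for it was too weak to exclude the explanation.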
